A study of Mus musculus with 54 samples.

How the data were processed

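RNA was measured by sequencing in mouse cerebellar tumours of 2 models and in normal cerebellum. SmoA1 mice carry an activated Smoothened transgene, and Ptc het mice carry 1 inactive copy of Ptch1. Normal cerebellum came from C57BL/6 mice and is called BL6. Mice received 1 Gy of radiation or sham treatment, and tissue was collected 5 h later. The labels state total RNA, RNeasy extraction and ribosomal RNA depletion.

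The deposited files hold raw read counts per gene, 1 file per library or part of a library, with the unmapped, multimapping, unassigned and ambiguous reads listed separately. Each file gives counts for both strands together and for each strand, in the layout of STAR's gene counts, with 53379 gene identifiers. The labels name the mm10 build and Cell Ranger 5.0.1, a program for single cells that writes another layout. The aligner of these files is not given in the sources used here. Symbols, biotypes and positions came from the GENCODE M21 annotation on GRCm38, which matched 53274 identifiers.

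The 54 files make 18 libraries. For BL6 and SmoA1 each numbered sample has 4 files, and for Ptc it has 1. The titles call the 4 files biological replicates, but they carry the same sample number. Counts of the 4 files varied no more than random draws from 1 library would, with a variance to mean ratio between 0.857 and 0.938 over genes with at least 40 counts. They were therefore summed and counted as 1 library. Each of the 6 groups then holds 3 libraries. The labels do not state that the numbered samples came from separate animals, so p-values measure only the spread between these samples.

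The unstranded column was used, because no single strand column held 80% of the counts in all 18 libraries. The alternative took the strand column with the larger total. Genes were filtered with filterByExpr and scaled with TMM in edgeR 4.0.16 under R 4.3.3. Each pair of groups was tested by the edgeR quasi-likelihood test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Differences between models in the change after 1 Gy were tested as interaction terms over 12 libraries. Counts scaled to library depth by edgeR (CPM) were scaled within each comparison, so a gene's CPM differs between comparisons. The difference was slight except where Ptc was scaled together with BL6 or SmoA1. CPM values from those fits differ widely from values in the other fits and are not comparable with them. For a gene at 0 in every library of a group, the fold is a lower bound against 3 counts over that group, and no fitted fold is given. The floors cover counting error only, while the SD and SE values include the spread between libraries.

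Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The camera test was repeated with an estimated correlation and with fry. There were 35 lists, 20 of pathways and 15 of marker genes, with 724 genes in all, and a list was tested where at least 3 members passed the filter. Lists, comparisons, the rule for named genes and most alternatives were chosen before the data were examined. The rule named Ptch1, Smo and Gli1 everywhere. It named the 6 largest increases and 6 largest decreases among called protein-coding genes with a mean of at least 1 CPM and no overlap between the libraries of the 2 groups. From each list it took up to 3 called members per direction by smallest p, or up to 2 members that did not pass. For interactions it took the 5 smallest p per direction. The text stops before the end of some of these rankings, and some genes of the rule are not reported here. Tnfaip2 and Cdkn1a for 1 Gy in SmoA1, and Cdkn1a, Plk3, Mycn, Gad2 and Slc32a1 for SmoA1 against BL6 in sham, fell outside the rule there and were chosen after their values were seen. The same holds for Slc32a1 for 1 Gy in Ptc.

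The alternatives were the DESeq2 1.42.0 Wald test, RLE and upper-quartile factors, no low-count filter, a mean of at least 1 CPM, the strand column, all 18 libraries in 1 fit, the sample number as a block, each library left out in turn, part 1 only, each part as a replicate, an adjusted p under 0.01, and a log2 fold change of at least 1. After the data were seen, offsets fitted along abundance with a loess span of 0.3 and leaving out both Ptc libraries numbered 2 were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

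The methods were tested on simulated counts with 200 genes changed by known folds, 100 at each of 2 sizes. The folds were set in the counts themselves. Recovery of changes in RNA was not tested where counts compress such changes. For 1 Gy in BL6, edgeR recovered 72 of 100 genes changed 2-fold and 90 changed 4-fold, with 7 false calls among 15505 genes. For 1 Gy in SmoA1 it recovered 60 and 93, with 6 false calls among 16194 genes. For 1 Gy in Ptc it recovered 11 of 100 genes changed 4-fold and 70 changed 16-fold, with 4 false calls among 19083 genes, while DESeq2 recovered 46 and 87 with 111 false calls. For SmoA1 against BL6 it recovered 65 and 93 at 2-fold and 4-fold in sham libraries (15853 genes) and 62 and 94 after 1 Gy (16446 genes). For the difference between SmoA1 and BL6 it recovered 29 and 73 at 2-fold and 4-fold (17754 genes). At 4-fold and 16-fold it recovered 8 and 45 for the difference between Ptc and BL6 (25504 genes) and 6 and 49 for that between Ptc and SmoA1 (26577 genes). For Ptc against BL6 it recovered 19 and 83 at 4-fold and 16-fold in sham libraries (22396 genes) and 41 and 86 after 1 Gy (22211 genes). In each of the 10 comparisons the camera test called a raised list of 25 genes and 0 of 20 unchanged lists. Simulated genes varied independently of each other, so this cannot test whether the preset correlation suits genes that move together.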

Results

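The counts describe the early response to radiation in 2 mouse models of medulloblastoma and in normal cerebellum, 5 h after 1 Gy or sham treatment. Each of the 6 groups holds 3 libraries. The 12 BL6 and SmoA1 libraries hold between 540652 and 842997 counts in genes, with 45.8% to 76.1% of reads unmapped. Of the uniquely mapped reads in those libraries, 70.4% to 75% lay over no annotated exon, and both strands were equally represented. The 6 Ptc libraries hold between 34124031 and 51330146 counts in genes, with 2.53% to 6.16% of reads unmapped and most counts on 1 strand. The median depth of the Ptc libraries was 61.9 times that of the others. Model and library type are therefore confounded wherever Ptc is compared with BL6 or SmoA1.

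The abundance profile also differed. In the Ptc libraries Actb lay between 795.7 and 2619 CPM, whereas in the BL6 and SmoA1 libraries it lay between 25 and 59.3 CPM. For protein-coding genes at 1 to 3 CPM per exonic kb in Ptc, the median density in BL6 and SmoA1 was 9.92, and for genes at 100 to 300 it was 16.4. Mitochondrial genes took 1.41% to 3.03% of the counts in Ptc and 0.0045% to 0.0135% in BL6 and SmoA1. Fold changes in BL6 and SmoA1 are reported as measured on this compressed scale, and levels there do not rank genes by abundance.

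**Figure D1:**
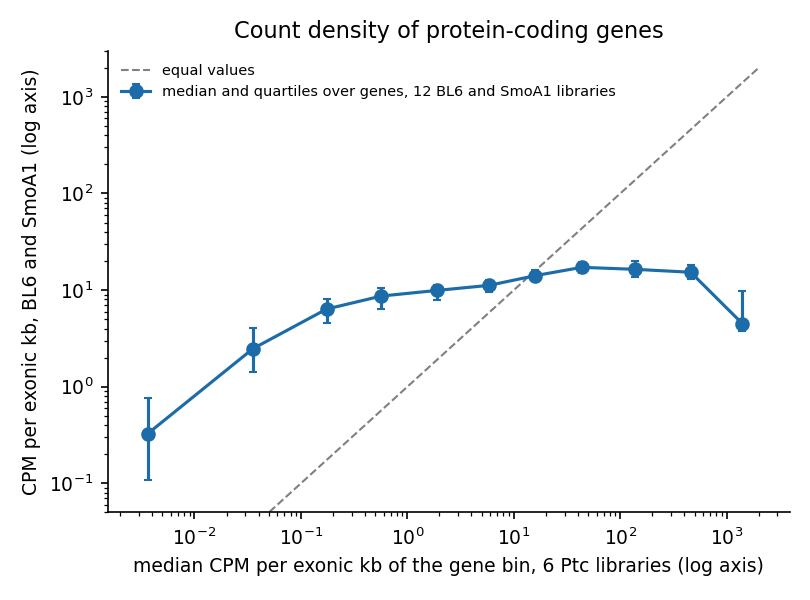
Median count density of protein-coding genes in the 12 BL6 and SmoA1 libraries (vertical log axis, CPM per exonic kb, bars from the lower to the upper quartile over genes) for bins of genes. Bins were set by each gene's mean density over the 6 Ptc libraries and are placed at the bin's median over genes (horizontal log axis). The median moves from 9.92 to 16.4 between the bins at 1 to 3 and at 100 to 300, and the dashed line marks equal values.

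The first comparison asks how SmoA1 tumour differed from normal cerebellum without radiation. Cell division genes were higher in the tumours. Cenpf, a kinetochore protein, stood at 208 ± 34.0 CPM against 23.3 ± 12.7 in BL6 (SD, n = 3 each), a 9.14-fold difference, and the proliferation marker Mki67 at 213 ± 30.6 against 36.6 ± 8.70. Dtl, which targets replication licensing factors for degradation, was 10-fold higher, Top2a 5.27-fold, the replication gene regulator E2f8 8.26-fold, and the replicative helicase subunit Mcm2 2.58-fold. The DNA repair genes Exo1, Fancd2 and Brca1 were 4.62-fold, 2.51-fold and 2.2-fold higher. Of the measured members, 35 of 40 in the G2/M list, 19 of 31 in the G1/S list and 16 of 37 in the DNA repair list were called higher and 0 lower, and 40, 21 and 16 were called higher when adjusted over the list alone. The camera adjusted p was 3.12e-26, 3.64e-11 and 4.81e-06 for these lists, and 0.0456 for each with an estimated correlation. These were the only 3 of the 130 list calls in the 10 comparisons that held with an estimated correlation.

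Some genes of hedgehog signalling and of granule neuron progenitors were also higher. Smo, the receptor component that SmoA1 mice carry as an active transgene (ENSMUSG00000001761, chromosome 6, 29735503 to 29761365 on GRCm38), stood at 94.2 ± 6.97 CPM against 45.3 ± 0.222 (log2 fold change 1.06 ± 0.18 SE, adjusted p = 0.000161). The pathway effector Gli1 was 1.73-fold higher at 100 ± 9.06 CPM (adjusted p = 0.00411), while Ptch1, the inhibitory receptor, was at 232 ± 14.2 against 212 ± 27.0 (adjusted p = 0.506). In the Sonic hedgehog target list, Ccnd2 (2.22-fold), Sfrp1 (2.01-fold), Mycn and Gli1 were among those higher, and Pax2, Prdm6 and Hhatl were lower, so that 5 of 20 members were called higher and 3 lower, against 6 and 3 when adjusted over the list alone. The list as a whole was not called (adjusted p = 0.188). Atoh1, the transcription factor that marks granule neuron progenitors, was 6.19-fold higher, Nhlh1 3.50-fold and Sox11 2.00-fold, and 8 of 21 progenitor genes were called higher, with the same number adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.221 with an estimated correlation). Without BL6 sham replicate 1 this list had an adjusted p of 0.0822. Hhatl lost its call without BL6 sham replicate 1 (adjusted p = 0.0924), SmoA1 sham replicate 1 (0.071) or SmoA1 sham replicate 2 (0.079), and Mycn without BL6 sham replicate 2 (0.0815).

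Many genes of mature cerebellar cells were lower. The interneuron genes Gad1, an enzyme of GABA synthesis, and Slc6a5, the neuronal glycine transporter, stood at 0.373 and 0.263 of the BL6 level, and Tfap2b, Gad2 and Slc32a1 were the other 3 of 10 interneuron markers called lower. The Purkinje genes Rgs8 and Slc1a6 stood at 0.537 and 0.405 of normal, and the granule neuron genes Chn2, Gabrd and Slc17a7 at 0.492, 0.509 and 0.514. Of the measured members, 9 of 12 mature granule neuron markers, 6 of 9 Purkinje markers and 5 of 10 interneuron markers were called lower (10, 6 and 6 adjusted over the list alone). Of the oligodendrocyte markers 6 of 13 were called lower, among them Mobp, Aspa and Opalin, and the myelin gene Mbp was called higher at 131 ± 20.6 against 87.2 ± 16.5 CPM (9 lower and 1 higher adjusted over the list alone). The 4 lists had adjusted p values of 0.00131, 0.00594, 0.00278 and 0.00106, and 0.258, 0.221, 0.258 and 0.191 as adjusted p with an estimated correlation. Mbp lost its call without BL6 sham replicate 2 (adjusted p = 0.105) and without SmoA1 sham replicate 2 (adjusted p = 0.0557). Slc32a1 lost its call without BL6 sham replicate 2 (0.0503), BL6 sham replicate 3 (0.0688) or SmoA1 sham replicate 2 (0.0532).

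Smaller groups differed too. The microglial genes Tyrobp, C1qb and Lyz2 were 3.73-fold, 2.23-fold and 1.98-fold higher, 3 of 17 markers both over all genes and adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.221 with an estimated correlation). C1qb and Lyz2 lost their calls when some single libraries were left out, C1qb with adjusted p values of 0.0821 without BL6 sham replicate 1, 0.151 without BL6 sham replicate 3 and 0.126 without SmoA1 sham replicate 1. Lyz2 reached 0.163 without BL6 sham replicate 1, 0.129 without BL6 sham replicate 2, 0.109 without SmoA1 sham replicate 1 and 0.0732 without SmoA1 sham replicate 2. The p53 targets Eda2r, Ckap2, Psrc1, Cdkn1a and Plk3 were higher, 5 of 32 members (6 adjusted over the list alone), with Eda2r at 85.5 ± 12.7 against 27.6 ± 5.74 CPM (list adjusted p = 0.0221, and adjusted p = 0.258 with an estimated correlation). Plk3 lost its call without BL6 sham replicate 1 (adjusted p = 0.119), BL6 sham replicate 2 (0.0914) or SmoA1 sham replicate 2 (0.114). Prlr, the prolactin receptor, stood at 5.49 ± 2.03 against 138 ± 13.2 CPM, and 2 of 9 choroid plexus and ependymal markers were lower, Prlr among them, with 2 also adjusted over the list alone. That list had an adjusted p of 0.026 (adjusted p = 0.221 with an estimated correlation), which was 0.0631 without BL6 sham replicate 2 and 0.0504 without SmoA1 sham replicate 2. Spic, Tmprss13 and Vrtn had no count in BL6 and were at least 17.3-fold, 14.8-fold and 12.3-fold higher, and Pdzph1, Cckbr and Glra3 had none in the tumours and were at least 24.2-fold, 22.5-fold and 34.0-fold lower. In all, 2705 of 16428 genes differed, 1161 higher and 1544 lower. DESeq2 called 1727, omitting the low-count filter gave 4422, and fitting all 18 libraries together gave 17.

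After 1 Gy, SmoA1 tumour differed from 1 Gy BL6 in 1175 of 16990 genes, 736 higher and 439 lower. Smo was 2.12-fold higher (87.2 ± 12.4 against 41.1 ± 3.51 CPM, adjusted p = 0.000771), Gli1 stood at 74.3 ± 22.6 against 52.3 ± 7.10 (adjusted p = 0.211) and Ptch1 at 208 ± 40.2 against 217 ± 9.39 (adjusted p = 0.897). Of the inflammatory genes 14 of 24 were called higher (19 adjusted over the list alone), with a list adjusted p of 1.08e-14 and an adjusted p = 0.0956 with an estimated correlation. Of the G2/M genes 20 of 40 were higher (29 adjusted over the list alone), with adjusted p = 9.96e-21 and adjusted p = 0.0956 with an estimated correlation. Gli1 passed without SmoA1 1 Gy replicate 1 (adjusted p = 0.033). DESeq2 called 702 genes.

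The next comparison asks what 1 Gy changed in normal cerebellum. Eda2r, a death receptor of the TNF receptor family and a p53 target (ENSMUSG00000034457, chromosome X, 97333840 to 97377216 on GRCm38), rose from 27.8 ± 5.77 to 86.9 ± 6.65 CPM (SD, n = 3 each; log2 fold change 1.66 ± 0.22 SE, adjusted p = 0.000269). Xist fell from 233 ± 20.7 to 121 ± 42.9 CPM (adjusted p = 0.00283), and the mean log2 CPM of the sex-linked list, most of it Y-linked genes, was 6.00 and 5.98 in 1 Gy replicates 2 and 4, 3.69 in 1 Gy replicate 3 and between 3.16 and 3.35 in the sham libraries. Sex-linked expression thus differed between the arms, so a change in BL6 cannot be fully told apart from a difference in sex. Smo, Gli1 and Ptch1 stood at 41.6 ± 3.60, 52.9 ± 7.27 and 220 ± 10.1 CPM after 1 Gy, against 45.6 ± 0.239, 58.8 ± 16.5 and 213 ± 26.9 in sham, each with adjusted p = 0.998. Of 30 p53 targets 21 had positive fold changes and 1 rose, with the same number adjusted over the list alone (camera adjusted p = 0.00806, and adjusted p = 0.538 with an estimated correlation). Of 34 G2/M genes 26 were positive and 0 rose, 1 when adjusted over the list alone (adjusted p = 0.00509, and adjusted p = 0.644 with an estimated correlation), with Mki67 at 66.7 ± 24.8 against 36.8 ± 8.72 CPM and Cenpf at 47.0 ± 17.2 against 23.4 ± 12.8 (adjusted p = 0.998 for both). The immediate early gene Fos was at 25.5 ± 3.14 against 43.0 ± 5.01, and the chaperone gene Hsp90ab1 at 42.8 ± 12 against 77.2 ± 5.34 CPM (adjusted p = 0.998 and 0.949).

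In BL6 edgeR called 2 of 15918 genes, with 634 at an unadjusted p under 0.05 where 796 were expected by chance, and DESeq2 called 1. Without BL6 sham replicate 2, 0 genes passed, with Eda2r at an adjusted p of 0.0543 and Xist at 0.151, and the count was 6 without 1 Gy replicate 3, sham replicate 1 or sham replicate 3 and 4 without 1 Gy replicate 4. The p53 list lost its call without 1 Gy replicate 2 (adjusted p = 0.102) and without 1 Gy replicate 4 (adjusted p = 0.139), and the G2/M list without 1 Gy replicate 2 (adjusted p = 0.102). Of 32 lists tested in BL6 these 2 were called, and without sham replicate 1 the WNT and Notch list (adjusted p = 0.0283) and the mature granule neuron list (0.0304) also passed, both lower. The sex-linked list, which had too few members past the filter in the full set, was tested and passed upward without 1 Gy replicate 3 (adjusted p = 5.3e-11) and without sham replicates 1 (0.0101), 2 (0.0178) and 3 (0.00321).

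The same treatment was then compared in SmoA1 tumours. Some inflammatory genes rose. Tnip3, an inhibitor of NF-kB signalling (ENSMUSG00000044162, chromosome 6, 65525313 to 65634040 on GRCm38), went from 3.68 ± 2.02 to 59.9 ± 15.6 CPM (log2 fold change 3.96 ± 0.41 SE, adjusted p = 4.21e-05). The adhesion molecule Vcam1 rose 1.72-fold to 129 ± 3.53 CPM, the NF-kB inhibitor Tnfaip3 1.88-fold and the cytokine Tgfb1 2.13-fold, and with Tnfaip2 these were the 4 of 23 inflammatory genes that rose, against 17 when adjusted over the list alone (camera adjusted p = 1.31e-12, and adjusted p = 0.165 with an estimated correlation). The interferon response genes Oas3, Mx1 and Zbp1 rose 4.4-fold, 2.67-fold and 2.19-fold, 3 of 26 members, against 8 adjusted over the list alone (adjusted p = 3.26e-08, and adjusted p = 0.188 with an estimated correlation). The activity-induced transcription factors Fosb, Nr4a3 and Npas4 rose 2.91-fold, 1.94-fold and 1.85-fold, 3 of 28 immediate early genes, against 7 adjusted over the list alone (adjusted p = 0.000698, and adjusted p = 0.188 with an estimated correlation). The neutrophil genes Mmp8 and Cxcr2 rose 3.31-fold and 2.65-fold, 2 of 3 measured markers, against 3 adjusted over the list alone (adjusted p = 0.00068, and adjusted p = 0.188 with an estimated correlation).

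A smaller set of genes fell. Ung, which removes uracil from DNA, dropped from 91.7 ± 12.1 to 41.8 ± 11.4 CPM, the histone chaperone subunit Chaf1a from 80.4 ± 20.6 to 37.8 ± 7.94 and the helicase subunit Mcm5 from 111 ± 12.4 to 65.4 ± 5.63. Mcm5 was the 1 of 31 G1/S genes that fell, against 8 adjusted over the list alone (adjusted p = 2.1e-07, and adjusted p = 0.249 with an estimated correlation). In the DNA repair list the checkpoint kinase gene Chek2 fell to 0.586 of the sham level, 1 of 37 members and also 1 adjusted over the list alone (adjusted p = 0.000159, and adjusted p = 0.281 with an estimated correlation). Of 40 G2/M genes 2 had positive fold changes and 0 fell by edgeR, both over all genes and adjusted over the list alone (adjusted p = 1.66e-06, and adjusted p = 0.281 with an estimated correlation). The progenitor transcription factor gene Sox11 fell to 0.660 of its sham level, and Vrtn, Fam186a, Mymx and Nkain3 fell to 0.140, 0.323, 0.242 and 0.509. Smo stood at 87.1 ± 12.4 against 93.6 ± 6.39 CPM, Gli1 at 74.2 ± 22.5 against 99.8 ± 9.69 and Ptch1 at 208 ± 39.9 against 231 ± 16.1, with adjusted p values of 0.862, 0.334 and 0.708. The Sonic hedgehog target list was not called (adjusted p = 0.0561), though it passed without SmoA1 sham replicate 2 (adjusted p = 0.019), without SmoA1 1 Gy replicate 3 (0.0439) and without SmoA1 sham replicate 1 (0.0472).

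Some genes of mature cerebellar cells rose. The interneuron genes Slc6a5 and Gad1 rose 3.36-fold and 2.2-fold, the Purkinje gene Calb1 1.69-fold, the granule neuron gene Chn2 1.87-fold and the oligodendrocyte gene Opalin 4.93-fold. These were 2 of 10, 1 of 9, 1 of 12 and 1 of 13 measured markers, against 3, 5, 5 and 4 when adjusted over the list alone. The lists had adjusted p values of 0.0242, 0.0177, 0.0032 and 0.00421, and 0.395, 0.414, 0.418 and 0.281 as adjusted p with an estimated correlation. Without SmoA1 1 Gy replicate 1 the interneuron, Purkinje and granule neuron lists stood at 0.13, 0.145 and 0.0834, without 1 Gy replicate 2 the Purkinje and granule neuron lists at 0.0855 and 0.0661, and without sham replicate 2 the interneuron list at 0.172. All 5 measured histone genes had positive fold changes, 0 rose by edgeR and 1 when adjusted over the list alone (adjusted p = 0.00481, adjusted p = 0.281 with an estimated correlation, and adjusted p = 0.111 without SmoA1 sham replicate 1).

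Among p53 targets Plk2, a stress-induced kinase, rose 1.87-fold, 1 of 32 members and 3 when adjusted over the list alone, and the list was not called (adjusted p = 0.114). Cdkn1a, the cell cycle inhibitor p21, stood at 45.0 ± 6.26 against 59.8 ± 9.89 CPM (adjusted p = 0.403). The other single members that rose were Birc3 (1.93-fold) among apoptosis regulators, Ndrg1 (2.70-fold) in the hypoxia list, Slc4a1 among erythrocyte markers, Dcn among fibroblast markers and Prlr among choroid plexus markers. In the migration list Cdh1, Cd44 and Plaur rose 2.85-fold, 1.82-fold and 2.18-fold and Sparc fell to 0.512 (4 higher and 1 lower adjusted over the list alone, list adjusted p = 0.0884). Bmp2 and Tgfb1 were the 2 of 32 BMP and TGF-beta genes that rose, with 2 also adjusted over the list alone (list adjusted p = 0.872). Slc10a6, Slc5a1, Vwa5b1 and Ptger3 rose 12.3-fold, 11.9-fold, 10.6-fold and 17.4-fold, and Fgb, a fibrinogen chain, was at least 19.1-fold higher, from 0 to 26.3 ± 3.2 CPM.

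In all, 363 of 16690 genes changed in SmoA1, 331 higher and 32 lower. DESeq2 called 225, omitting the low-count filter gave 969, and fitting all 18 libraries together gave 0. The count was 109 without SmoA1 1 Gy replicate 2, 158 without 1 Gy replicate 1 and 237 without sham replicate 1. The median log2 fold change was 0.30 in the 2782 genes lowest in Ptc, with 220 calls up and 7 down, and -0.08 in the 2782 genes highest there. With offsets along abundance the former had a median of -0.01, with 100 calls up and 43 down. Of the 43 genes named above as changed, 12 passed whichever single library was left out: Tnip3, Fgb, Slc10a6, Slc5a1, Vwa5b1, Ptger3, Vcam1, Oas3, Cdh1, Ndrg1, Gad1 and Slc6a5. Without 1 Gy replicates 1, 2 and 3 in turn, 18, 17 and 34 of the 43 passed, and without sham replicates 1, 2 and 4, 23, 33 and 26 passed. The highest adjusted p was 0.259, for Opalin without 1 Gy replicate 1. The lymphocyte list passed upward without 1 Gy replicate 1 (adjusted p = 0.0148), 1 Gy replicate 3 (0.0474) or sham replicate 1 (0.00985), the erythrocyte list upward without 1 Gy replicate 2 (0.0469) and the sterol list downward without 1 Gy replicate 3 (0.0474).

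**Figure D2:**
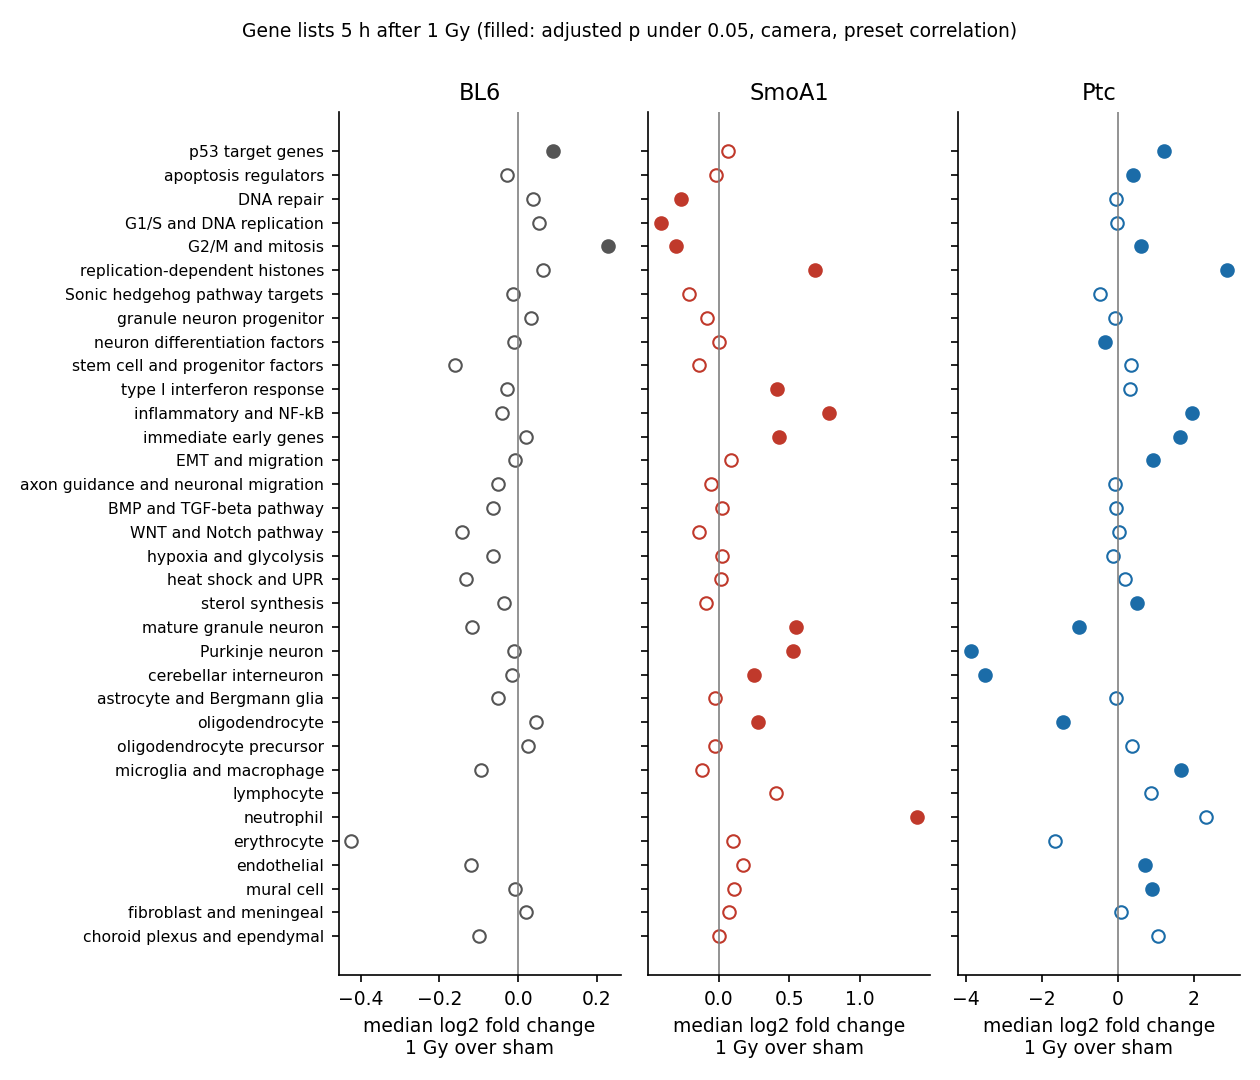
Median log2 fold change of 1 Gy over sham for the measured members of each gene list (horizontal axis, a separate scale for each model) in BL6, SmoA1 and Ptc, from 3 libraries per group. Filled points have a camera adjusted p under 0.05 with the preset correlation. The inflammatory list has a median of -0.04 in BL6, 0.78 in SmoA1 and 1.94 in Ptc. BL6 and SmoA1 lie on a compressed scale, so sizes there are not comparable with Ptc.

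In Ptc tumours 1 Gy was compared with sham in the same way. Immediate early genes, p53 targets and inflammatory genes shifted up as lists. Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273 on GRCm38) stood at 213 ± 96.2 CPM against 6.21 ± 2.23 (SD, n = 3 each; log2 fold change 5.10 ± 0.49 SE, adjusted p = 0.484) and Fosb at 66.0 ± 33.9 against 0.794 ± 0.533 (adjusted p = 0.685). Cdkn1a (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727 on GRCm38) was at 377 ± 92.6 against 62.9 ± 6.12 (log2 fold change 2.59 ± 0.28 SE, adjusted p = 0.526) and the death receptor gene Tnfrsf10b at 11.7 ± 6.48 against 1.91 ± 0.0506 (adjusted p = 0.685). The cytokine genes Il6 and Il1a stood at 8.14 ± 8.82 against 0.0147 ± 0.0128 and at 10.4 ± 4.66 against 0.945 ± 0.411, the myeloid genes Cd14 and C1qa at 88.0 ± 78.2 against 1.61 ± 0.397 and at 136 ± 86.1 against 38.5 ± 13.8, and Spp1 at 114 ± 67.4 against 17.0 ± 5.90, each with an adjusted p of 0.685. As lists, immediate early genes (27 of 28 positive), p53 targets (29 of 32) and inflammatory genes (24 of 27) shifted up, with adjusted p values of 2.71e-14, 2.71e-14 and 7.62e-17, and adjusted p = 0.393 for each with an estimated correlation. Of their members 0 rose by edgeR over all genes, and 10, 10 and 20 rose when adjusted over the list alone. These 3 lists kept their calls whichever single library was left out, but with fry 0 of 34 lists passed in Ptc.

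Other lists were called in Ptc with the preset correlation, and for each of the following the adjusted p was 0.789 with an estimated correlation. Microglial markers (16 of 17 positive, adjusted p = 1.83e-05) and migration genes (28 of 32, adjusted p = 3.86e-06) shifted up, with 1 and 4 members higher when adjusted over the list alone. Replication-dependent histones shifted up (18 of 19 positive, adjusted p = 3.64e-06), with list means of 3.82 and 1.62 log2 units above the sham mean in 1 Gy replicates 2 and 3 and -0.02 in replicate 1. In 1 Gy replicate 2, 5.82% of the counts lay in genes that overlap ribosomal RNA and 8.58% in the top 10 genes, against 0.057% to 0.518% and 2.97% to 3.84% in the other Ptc libraries. G2/M genes (40 of 40 positive, adjusted p = 2.29e-06), apoptosis regulators (adjusted p = 0.0124), sterol synthesis genes (0.00301), endothelial markers (0.00796) and mural cell markers (0.0497) shifted up. Purkinje (9.08e-06), interneuron (0.000359), oligodendrocyte (0.00796) and mature granule neuron markers (0.0339) and neuron differentiation factors (0.0339) shifted down, with 8 of 11 Purkinje markers lower when adjusted over the list alone and 0 over all genes. The Purkinje gene Rgs8 stood at 33.3 ± 13.5 against 604 ± 755 CPM, Slc1a6 at 4.17 ± 2.67 against 78.6 ± 96.8 and the interneuron gene Gad2 at 3.49 ± 3.34 against 65.9 ± 86.5 (adjusted p = 0.685 for each). The Purkinje list mean in sham replicate 2 was 2.01 log2 units above the sham mean, and the G1/S and G2/M list means there were -1.56 and -2.03.

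Without Ptc sham replicate 2, the G2/M list had an adjusted p of 0.904, apoptosis regulators 0.148, oligodendrocyte markers 0.854, mature granule neuron markers 0.854 and interneuron markers 0.0525. The medians of the last 3 went from -1.46 to -0.04, from -1.03 to 0.09 and from -3.50 to -1.83. Leaving the same library out gave calls downward for G1/S genes (adjusted p = 1.27e-11, from 0.454), DNA repair genes (2.37e-05, from 0.759), Sonic hedgehog targets (0.001, from 0.252) and granule neuron progenitor genes (0.0066, from 0.59), and upward for erythrocyte (0.00681), hypoxia (0.00889) and heat shock genes (0.0115). In the full set of libraries the G1/S and DNA repair lists had medians of -0.03 and -0.05 while their tests pointed up. Without 1 Gy replicate 2 the endothelial, mural, mature granule neuron and differentiation factor lists stood at 0.575, 0.938, 0.499 and 0.621, and without 1 Gy replicate 1 the sterol and oligodendrocyte lists at 0.459 and 0.352. Without sham replicate 1 the endothelial and mural lists stood at 0.182 and 0.352, without 1 Gy replicate 3 the mature granule neuron list at 0.22, and without sham replicate 3 the endothelial, mural, mature granule neuron and differentiation factor lists at 0.05, 0.181, 0.0592 and 0.0622. The G1/S list passed upward without sham replicate 1 (0.000911) and sham replicate 3 (0.038), and the DNA repair list without sham replicate 1 (0.0114). With both Ptc libraries numbered 2 left out, 8 of the 16 list calls held. The microglial, migration and mural lists then stood at 0.121, 0.105 and 0.0608, the interneuron list at 0.0224 and the histone list at 0.000503. Further calls came without 1 Gy replicate 1 (upward, neutrophil 9.21e-08, interferon 0.000687, oligodendrocyte precursor 0.0179, progenitor factors 0.019 and choroid plexus 0.0196), without 1 Gy replicate 2 (downward, fibroblast 0.00294 and astrocyte 0.00531), without sham replicate 1 (downward, fibroblast 0.00133 and astrocyte 0.0178, and upward, neutrophil 0.0462) and without sham replicate 3 (upward, neutrophil 0.0271). Ptch1 was at 133 ± 19.4 CPM after 1 Gy against 193 ± 5.62, Smo at 148 ± 51.2 against 123 ± 80.7 and Gli1 at 126 ± 74.7 against 158 ± 108, with adjusted p values of 0.685, 0.914 and 0.916. By edgeR 0 of 19571 genes passed in Ptc, with 1421 at an unadjusted p under 0.05 where 979 were expected by chance, and DESeq2 called 321, 211 higher and 110 lower. The simulated data for this comparison gave 111 false DESeq2 calls and 4 false edgeR calls.

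**Figure D3:**
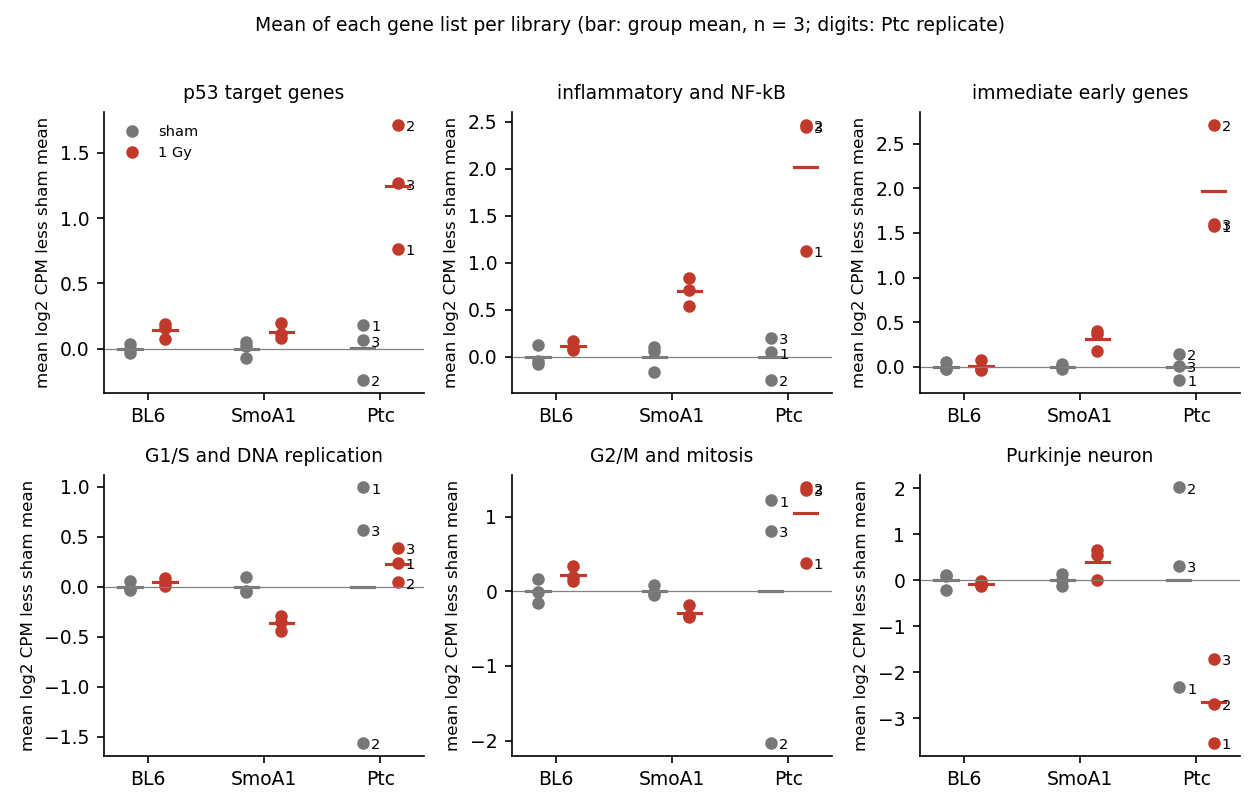
Mean log2 CPM of 6 gene lists in each library, less the mean of the sham libraries of the same model (vertical axis, log2 units), with 3 libraries per group, bars at group means and the replicate number beside each Ptc point. Ptc sham replicate 2 lies at 2.01 in the Purkinje panel and at -2.03 in the G2/M panel.

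The response to 1 Gy was also compared between the models. The difference in sex-linked expression between the BL6 arms enters each comparison with the change in BL6. Between SmoA1 and BL6, 193 of 18188 genes differed in their change, 181 with a larger value in SmoA1 and 12 with a smaller one. The anion exchanger gene Slc26a7 went from 9.77 ± 4.72 to 56.7 ± 8.48 CPM in SmoA1 and from 69.4 ± 9.13 to 59.3 ± 8.80 in BL6 (difference of log2 fold changes 2.71 ± 0.37 SE, adjusted p = 0.000307). Vwa5b1, the desmosome component gene Ppl and the actin-severing protein gene Scin had differences of 3.52, 2.08 and 3.35. Eda2r stood at 83.7 ± 12.7 CPM in sham SmoA1 and 81.2 ± 11.5 after 1 Gy, so that its change was smaller than in BL6 by 1.70 ± 0.29 log2 units (a difference of -1.70, adjusted p = 0.00265). Prr12, Nfxl1, Mki67 and the mitotic gene Hmmr had differences of -1.19, -1.17, -1.19 and -2.24. Mki67 went from 209 ± 30.6 to 168 ± 11.5 CPM in SmoA1 and from 35.9 ± 8.45 to 64.8 ± 23.9 in BL6.

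As lists, G2/M, G1/S and DNA repair genes moved lower in SmoA1 than in BL6 (adjusted p = 1.6e-09, 1.25e-06 and 0.000347, and 0.0573, 0.0573 and 0.11 as adjusted p with an estimated correlation). Inflammatory and interferon genes moved higher (1.46e-05 and 3.34e-05, each with adjusted p = 0.0573 with an estimated correlation). The 3 cell cycle and repair lists held 2, 1 and 0 genes that differed over all genes and 4, 3 and 0 adjusted over the list alone, and the inflammatory and interferon lists 0 and 0 against 5 and 5. DESeq2 called 101 genes, omitting the low-count filter gave 449, and offsets along abundance gave 91. The count was 83 without BL6 sham replicate 1, 86 without SmoA1 1 Gy replicate 2, 88 without BL6 1 Gy replicate 4, 100 without BL6 sham replicate 2, 112 without BL6 sham replicate 3, 126 without SmoA1 1 Gy replicate 1 and 291 without SmoA1 1 Gy replicate 3. With 1 of the 12 libraries left out, Mki67 passed 3 times, Hmmr 4 times and Nfxl1 7 times, with highest adjusted p values of 0.199 (without BL6 1 Gy replicate 2), 0.177 (without BL6 1 Gy replicate 4) and 0.104 (without BL6 1 Gy replicate 3), and the other 6 named genes passed in every case.

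Changes in BL6 and SmoA1 lie on the compressed scale, so differences from Ptc also hold the difference between the library types. Ptc differed from BL6 in the change of 2 of 26305 genes, Fos (5.86 ± 0.53 log2 units, adjusted p = 0.00197) and Fosb (6.71 ± 0.84, adjusted p = 0.0412). In that fit Fos went from 12.7 ± 4.76 to 445 ± 198 CPM in Ptc and from 19.4 ± 1.73 to 11.6 ± 1.73 in BL6. Ptc differed from SmoA1 in 1 of 27377 genes, Cdkn1a (3.16 ± 0.36, adjusted p = 0.0275), which went from 131 ± 13.5 to 799 ± 196 CPM in Ptc and from 28.3 ± 6.07 to 19.3 ± 3.00 in SmoA1. The counts ranged from 1 to 63 for the first and from 0 to 91 for the second with 1 library left out, both highest without Ptc sham replicate 1, and the second was 0 without Ptc sham replicate 2. DESeq2 called 50 and 112 genes. Fos kept its call in each of those fits, while Fosb passed in 4 of 12 and Cdkn1a in 4 of 12, with Fosb at an adjusted p of 0.34 without BL6 1 Gy replicate 4 and Cdkn1a at 0.209 without SmoA1 1 Gy replicate 3.

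The genes called after 1 Gy did not overlap between the models. Of the genes tested in both, BL6 and SmoA1 shared 0 of 1 and 231 that rose and 0 of 1 and 26 that fell, and by edgeR Ptc had 0 calls to share, although DESeq2 calls shared 21 genes between models. The sets with 1 or 0 calls leave this overlap without a usable test. Across 15026 genes, which are not independent replicates, Pearson's r between the fold changes in BL6 and SmoA1 was -0.041, between BL6 and Ptc -0.009 over 15350 genes, and between SmoA1 and Ptc 0.048 over 16327 genes.

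Ptc tumour and BL6 cerebellum differed in 17030 of 22832 genes without radiation and in 16631 of 22991 after 1 Gy by edgeR, values that hold the difference between the library types. In sham libraries Smo stood at 239 ± 163 CPM in Ptc against 22.6 ± 0.386 in BL6, Gli1 at 308 ± 216 against 29.1 ± 7.76 and Ptch1 at 365 ± 32.2 against 106 ± 12.7. After 1 Gy Smo stood at 284 ± 92.3 against 20.5 ± 2.19, Gli1 at 242 ± 138 against 26.0 ± 3.69, and Ptch1 at 256 ± 32.2 against 108 ± 7.77, a log2 difference of 1.24 that was -0.11 with upper-quartile factors. The median of all genes was -0.23 in sham and -0.16 after 1 Gy, and it was -1.55 and -1.52 with upper-quartile factors.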

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

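No test in this part was chosen after its result was seen, but Slc32a1 in Ptc was named after its values were seen.

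The change after 1 Gy differed between SmoA1 and BL6 for 193 genes by the interaction test. The log2 differences were -1.19 for Prr12, -1.17 for Nfxl1, -1.19 for Mki67, -2.24 for Hmmr and -1.70 for Eda2r, and 2.71 for Slc26a7, 3.52 for Vwa5b1, 2.08 for Ppl and 3.35 for Scin. Of 30 splits of the 12 libraries, 2 gave as many genes, the real one included, so chance was not excluded by this count. The other one, the highest, gave 216 genes. It kept the SmoA1 groups and exchanged BL6 1 Gy replicate 2 and BL6 sham replicate 2, so it still holds the change in SmoA1 and says little about chance.

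Ptc and BL6 differed in the change of 2 genes, Fos by 5.86 and Fosb by 6.71 log2 units. Of 30 splits 5 gave as many genes, with 27 in the highest other, so chance was not excluded. Because that is above the real count, the number of calls does not set treatment apart from other differences among these libraries. Ptc and SmoA1 differed in 1 gene, Cdkn1a, by 3.16 log2 units. Of 30 splits 3 gave as many, with 1 in the highest other, so chance was not excluded there either.

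The share of uniquely mapped reads lying over more than 1 gene was 0.6 percentage points higher after 1 Gy than in sham in Ptc, as a difference of means, and this was 1 of 12 checks of read classes. It was 5.32 ± 0.441% against 4.72 ± 0.163% (SD, n = 3 each), and the difference was not tested.

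Camera called 16 of 34 gene lists in Ptc tumours after 1 Gy at the preset correlation, and 0 with an estimated correlation or with fry, while 0 genes passed by edgeR, with 1421 at an unadjusted p under 0.05 and 321 called by DESeq2. Sham replicate 2 was rich in transcripts of cerebellar neurons and poor in those of dividing cells, and normal tissue in that library may account for part of this. Without it, 3 of 4 lists (p53 targets, inflammatory genes and immediate early genes) were still called higher at the preset correlation, so that library alone does not account for those 3, while the G2/M list was lost. Of the 4 neuron and oligodendrocyte lists 1, the Purkinje list, was still called lower without it, with a median of -2.18 against -3.88 with it. The interneuron list was not called (adjusted p = 0.0525) and its median went from -3.50 to -1.83. The medians of the mature granule neuron and oligodendrocyte lists went to 0.09 and -0.04. Gad2 lay between 4.01 and 165 CPM in sham with a mean of 65.9, so a sham library besides the highest also exceeded the 1 Gy maximum of 7.27. The same held for Slc32a1 (3.08 to 126, mean 52.6, 1 Gy maximum 6.18). Normal tissue in the sham libraries stays open for all 4 lists, beside a response to radiation.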

How the results depend on the processing

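Offsets along abundance and leaving out both Ptc libraries numbered 2 are tests chosen after the data were seen. Counts below are called genes, in the order 1 Gy in BL6 (2), SmoA1 (363) and Ptc (0), the differences SmoA1 less BL6 (193), Ptc less BL6 (2) and Ptc less SmoA1 (1), and SmoA1 against BL6 in sham (2705) and after 1 Gy (1175), with results that stayed within 1.5 times left out. In simulated counts edgeR recovered 72 and 60 of 100 genes changed 2-fold in BL6 and SmoA1, and 11 of 100 changed 4-fold in the deeper Ptc libraries, so smaller changes can be missed. Those folds were set in the counts, so changes in RNA may be missed more often on the compressed scale of BL6 and SmoA1. The cause of a move was not tested unless given.

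DESeq2 gave 1, 225, 321, 101, 50, 112, 1727 and 702. Omitting the low-count filter gave 16, 969, 1, 449, 7, 7, 4422 and 2235, with more genes tested. A mean of at least 1 CPM gave 8 in BL6, 614 in SmoA1, and 4162 and 1958 for SmoA1 against BL6. The strand column gave 0 in BL6 and 174 in SmoA1, 79, 1 and 0 for the differences, and 1447 and 612 for SmoA1 against BL6, with fewer genes tested. All 18 libraries together gave 0, 0, 1152, 0, 9, 3, 17 and 0. That fit shares 1 spread per gene across all groups. In the separate fits of 1 Gy in BL6, SmoA1 and Ptc the common spread (edgeR's biological coefficient of variation) was 0.07, 0.10 and 0.53. A shared spread therefore suits neither library type. Part 1 only, with fewer counts, gave 0 in BL6 and SmoA1, 12, 1 and 0 for the differences, and 375 and 62. Each part as a replicate gave 354 for SmoA1 less BL6, and 1316 and 598. Upper-quartile factors gave 1 for Ptc less BL6, and RLE factors 0 for Ptc less SmoA1. Offsets gave 91 for SmoA1 less BL6, and leaving out both Ptc libraries numbered 2 gave 8 for each Ptc difference. An adjusted p under 0.01 gave 128 in SmoA1, 56, 1 and 0 for the differences, and 1732 and 695. A log2 fold change of at least 1 gave 1 in BL6 and 1555 for SmoA1 against BL6 in sham.

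With the sample number as a block the counts were 7 in BL6, 551 in SmoA1, and 0 for each Ptc difference. The labels do not pair the libraries, and deviations of libraries with the same number correlated across genes with Pearson's r between 0 and 0.174, against -0.215 to 0.174 for different numbers.

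With 1 library left out, counts ranged from 0 to 6 in BL6, 109 to 445 in SmoA1, 83 to 291 for SmoA1 less BL6, 1 to 63 for Ptc less BL6 and 0 to 91 for Ptc less SmoA1. For Ptc against BL6 they ranged from 9771 to 14873 in sham (17030) and from 10585 to 14323 after 1 Gy (16631). The overlap of calls between models (0) was 1 without the low-count filter and 21 with DESeq2. The number of list calls (130) was 3 with an estimated correlation and 80 with fry, which are not all the same lists. For 1 Gy fry called 0 lists in BL6, 8 in SmoA1 (5 of the 12 called by camera among them) and 0 in Ptc. It called 7 for SmoA1 less BL6, 1 for Ptc less BL6 and 0 for Ptc less SmoA1, and for SmoA1 and Ptc against BL6 15 and 20 in sham and 11 and 18 after 1 Gy. The share of calls higher in Ptc than BL6 was 22.6% and 22.9% with upper-quartile factors and 68.1% and 68.4% with the strand column, and Ptch1 after 1 Gy was -0.11 with upper-quartile factors.

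In Ptc after 1 Gy some lists changed direction. Without both libraries numbered 2, the DNA repair (adjusted p = 0.00014), G1/S (2.87e-09), G2/M (0.112) and oligodendrocyte precursor (0.0229) lists pointed down and the differentiation factor (0.407) and granule neuron (0.261) lists up. With 1 library left out the adjusted p ranged from 2.37e-05 to 0.94 for DNA repair, from 1.27e-11 to 0.763 for G1/S and from 0.000921 to 0.621 for differentiation factors. The ends 2.37e-05 and 1.27e-11, without sham replicate 2, pointed down, and 0.621, without 1 Gy replicate 2, pointed up.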

Other observations

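The tests of lost reads, of genomic DNA and of the share of tumour cells, and the offsets along abundance, were chosen after the data were seen.

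After 1 Gy, more gene groups separated SmoA1 tumour from BL6 cerebellum than dividing-cell and inflammatory genes alone. Of 25 measured interferon response genes 4 were higher and 0 lower, also 4 adjusted over the list alone (adjusted p = 8.72e-05, and adjusted p = 0.166 with an estimated correlation). Of 28 immediate early genes 7 were higher, 12 adjusted over the list alone (adjusted p = 7.06e-05, and adjusted p = 0.142 with an estimated correlation). Of 32 migration genes 8 were higher, 9 adjusted over the list alone (adjusted p = 0.000194, and adjusted p = 0.142 with an estimated correlation). Of 17 microglial markers 2 were higher, 3 adjusted over the list alone (adjusted p = 0.000198, and adjusted p = 0.134 with an estimated correlation). The mature granule neuron list, with 9 of 12 members lower in the sham comparison, had 0 of 12 called by edgeR after 1 Gy and a list adjusted p of 0.651.

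The change after 1 Gy in Ptc was also compared with that in the other models list by list. Differences from Ptc also hold the difference between the library types, because BL6 and SmoA1 lie on the compressed scale. Against BL6, inflammatory genes (adjusted p = 8.1e-14), immediate early genes (4.69e-14) and p53 targets (2.31e-11) moved higher, with adjusted p = 0.171, 0.121 and 0.223 with an estimated correlation, and Purkinje markers moved lower (3.31e-05, and adjusted p = 0.59 with an estimated correlation). Against SmoA1, p53 targets (5.22e-10), immediate early genes (1e-09) and inflammatory genes (6.62e-06) moved higher, with adjusted p = 0.481, 0.324 and 0.605 with an estimated correlation. Of the p53 targets 0 of 32 differed from BL6 by edgeR and 1 from SmoA1, Cdkn1a, against 7 and 9 adjusted over the list alone. Between SmoA1 and BL6, mature granule neuron (adjusted p = 0.00559), Purkinje (0.00887), interneuron (0.0316) and oligodendrocyte (0.0379) markers moved higher in SmoA1, with 1, 0, 2 and 0 members over all genes, 4, 6, 3 and 3 adjusted over the list alone, and adjusted p = 0.352, 0.32, 0.32 and 0.32 with an estimated correlation. The interneuron list lost its call without BL6 1 Gy replicate 3 (0.0948), BL6 sham replicate 2 (0.107), SmoA1 1 Gy replicate 1 (0.0795) or SmoA1 sham replicate 2 (0.119), and the oligodendrocyte list reached 0.155 without BL6 1 Gy replicate 3. In Ptc the lists for BMP and TGF-beta (median -0.05, mean -0.02, test up), hypoxia (-0.14, 0.11, up), axon guidance (-0.08, 0.11, down), WNT and Notch (0.02, 0.06, down) and fibroblasts (0.08, -0.64, down) had a median, mean and test that differed in sign, and none of them was called.

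The gene profile of the BL6 and SmoA1 libraries was flat. The slope of log2 CPM per kb on that in the Ptc 1 Gy libraries was at most 0.213 among the 12 libraries. Shallower sequencing is argued against by Ptc sham libraries thinned to the same depth, whose lowest slope was 0.817. Genomic DNA as the source is argued against by genes without a Ptc count, whose mean density was 0.00934 of that of genes at 1 to 3 CPM per kb. Loss of reads from abundant transcripts before counting may account for it, but the slope restates the flat profile and so cannot test this. How such reads might have been lost was not tested. Why most unique reads in these libraries lay over no exon, and why both strands were equal, was not tested. No biological explanation was tested.

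More genes rose than fell in SmoA1 tumours after 1 Gy, 91.2% of 363 calls, against 78.4% of 292 with offsets fitted along abundance, and 229 genes were called both ways. In the 2782 genes lowest in Ptc, 100 then rose and 43 fell with a median of -0.01, against 220 and 7 with a median of 0.30, so a difference between libraries that depends on abundance may account for part of the excess. The mature granule neuron and Purkinje markers, with median log2 fold changes of 0.55 and 0.53 at median Ptc densities of 44.8 and 31 CPM per kb, go against the trend, because genes above 19.4 CPM per kb had a median of -0.08. A smaller share of tumour cells would raise the markers of cell types that are scarcer in tumour than in normal cerebellum. The marker lists moved apart (permutation p = 0.00071, 100000 permutations), with microglial markers at -0.11. Microglial genes were higher in SmoA1 than in BL6 in sham, however, so this test cannot decide. It also takes genes that move together as independent. Members under 10 CPM per kb leave out the mature granule neuron and Purkinje lists. Among them the medians were positive in each of 9 lists, with microglial markers at 0.25 and choroid plexus and ependymal markers at 0.005 (permutation p = 0.87). These medians were taken without offsets, and the trend along abundance itself raises the genes lowest in Ptc, so they cannot decide either. A smaller share and a response to radiation both stay open.

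The 10 splits of 6 libraries are too few for a share under 0.05. The real groups gave 2 genes for 1 Gy in BL6 and the highest other split 24, with 4 splits at least as large. Another split called more genes than the real groups, so this count does not set treatment apart from other differences among the BL6 libraries. The real groups gave 363 against 1 for 1 Gy in SmoA1, and 0 against 0 by edgeR for 1 Gy in Ptc, where all 10 splits gave 0. For SmoA1 against BL6 they gave 2705 against 0 in sham and 1175 against 4 after 1 Gy, and for Ptc against BL6 17030 against 0 and 16631 against 0.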
